A study of Macaca mulatta with 5 samples.

How the data were processed

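RNA was measured in single nuclei of frozen claustrum tissue of 2 male rhesus macaques with the 10x Genomics 3' V3 kit. There were 5 libraries, 2 from the 17-month animal and 3 from the 18-month animal, and no treatment. The deposited matrices hold raw UMI counts per gene and nucleus barcode, made with Cell Ranger 5.0.1 per the file headers. Per the labels, the authors' processing notes name CASAVA 1.8, Cell Ranger and Seurat and the builds Mmul_10 and mm10, while the gene identifiers in the tables are those of macaque only. The barcode filter of the authors is not stated. Of 21761 gene identifiers, 16548 had a symbol in the files and 712 had one in a table of identifiers and symbols. The identifier served as name for 4594, among them 93 whose symbol another identifier already bore.

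Nuclei with fewer than 500 genes (359 nuclei) were removed, and the limit of 5% mitochondrial UMIs removed none, the highest share being 2.54%. Scrublet (in scanpy 1.11.5) scored likely doublets. Its automatic threshold called between 0.15% and 3.35% of a library and was not used. Instead, the highest-scoring nuclei were removed at 0.8% per 1000 nuclei of a library, 2593 in all. The kept nuclei numbered 7461 and 7346 in the 17-month libraries and 7409, 8812 and 6025 in the 18-month libraries.

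Genes were split at random into 2 sets of equal size (seed 1), and the 2000 most variable genes of 1 set, without any listed gene, were used for clustering. Counts were scaled to 10000 per nucleus and log-transformed, 30 principal components were corrected for library with a Harmony-style method written for this work, and nuclei were joined to 15 nearest neighbours and clustered with Leiden (igraph 0.11.9) at resolution 1.0. Excitatory and inhibitory nuclei were clustered again at resolution 0.6. This gave 28 broad, 12 excitatory and 15 inhibitory clusters. Clusters were named by marker genes fixed before the data were examined, from marker scores of at least 0.5. Each score was divided by the highest score of its class among clusters not set aside for few nuclei or low UMIs. The highest of these clusters is therefore at 1.0 in every scored class by construction. The next unrelated class had to score under 0.6 in broad clusters and at least 0.15 lower in subclasses. In subclasses, over 60% of the markers had to be on, at 10 CPM or more and 25% or more of the highest cluster. The top 10 genes were recorded but did not enter the rule. The thresholds of this naming were set and revised over 3 versions after clusters had been seen. Broad clusters 5 and 12 each held 1 marker of another broad class among their top 10 genes (THEMIS and FOXP2) and 0 excitatory broad markers. They hold excitatory markers there only if subclass markers (THEMIS, GLP2R, FOXP2, SEMA3E) count as excitatory. Other named clusters also had 0 own markers there, such as broad clusters 2 and 7. Inhibitory cluster 12 scored as VIP-type but had more markers of the other CGE type among its top genes, and it was kept in the CGE-like class only. Clusters with fewer than 50 nuclei, or with a median of UMIs below 1/3 of that of their libraries, stayed unnamed. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

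Raw counts were summed per library and class, with at least 20 nuclei per sum, and tested with edgeR 4.0.16 (TMM, filterByExpr, robust quasi-likelihood fit) in R 4.3.3, with tables read by the package data.table (1.17.8). Comparisons of cell types had the library as a block, tested only genes not used for clustering or naming, and called genes at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. The 4 glial classes shared 1 fit of 20 sums. The animals were compared within each class at an adjusted p under 0.05 with no fold threshold, on 2 against 3 sums. Gene lists, 18 in all and fixed before the data were examined, were tested with camera (limma 3.58.1, voom) at its preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. Lists of receptors, neuropeptides, channels, calcium-binding proteins, axon guidance genes and rodent claustrum genes were used for neurons, lists of uptake, myelin lipid and immune genes with glutamate and GABA receptors for glia, and lists of activity-regulated, heat shock and mitochondrial genes for the animals.

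Genes are named by a rule fixed before the data were examined. It takes up to 4 called members of each list with the largest fold change and the same direction in each library. It adds the 10 highest and 10 lowest called genes of each neuron comparison, the 5 highest of each glial class and the 5 highest and 5 lowest of each class between animals, at 20 CPM or more in the higher group. FKBP5 and the genes of single clusters were chosen after their values were seen, and not every gene the rule gives is printed. Genes with no count in a group are compared with a floor of 3 counts over the group, and genes with 1 to 3 counts are given as ratios with exact 95% intervals. Shares have exact Clopper-Pearson 95% intervals.

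Alternatives tried were DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter on low counts, sums thinned to the smallest total, each library left out in turn, the block left out or added, sums per animal, lower clustering resolution (0.6 and 0.3), no library correction, at least 1000 genes per nucleus and no doublet removal. Subtraction of a background profile (that of the low-UMI cluster of each library), other references for claustrum-like neurons and a CGE-like class without inhibitory cluster 12 were added after the data had been seen. Without a 17-month library, 1 library of that animal is left and is assumed to vary like the others. Groups of 2 and 3 libraries are too small for a test of outlying libraries.

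The tests were tested on simulated data with 200 changed genes. For excitatory against inhibitory neurons, 99 of 100 genes changed 3-fold were found, for claustrum-like neurons 95 and for MGE-like against CGE-like neurons 100. Between the animals, 78 of 100 genes changed 2-fold were found in excitatory neurons with 21 false calls, and 51 of 100 in endothelial cells with 6 false calls. Clustering was tried on simulated nuclei of 8 classes, each with 400 genes raised 6-fold. All nuclei fell in a cluster of their own class, a measure that does not fall when a class is split. The 8 classes gave 13 clusters with library correction and 26 without, with an adjusted Rand index of 0.717 and 0.457. Uniform classes were thus split, so several clusters of 1 class need not be distinct types. Libraries were checked for identity by shared barcodes, 11 to 36 per pair. Mural cells, fibroblasts and committed precursors were not compared between animals, and unnamed clusters were left out of the main comparisons.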

Results

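Single nuclei were profiled from claustrum tissue, a thin sheet of grey matter between the insular cortex and the striatum, of 2 healthy male rhesus macaques aged 17 and 18 months. The 17-month animal gave 2 libraries and the 18-month animal gave 3 libraries, so libraries of an animal are repeats on that animal and each age is 1 animal. The files held 40005 nucleus barcodes and raw counts of unique molecular identifiers (UMIs). The 17-month libraries totalled 50993715 and 47512670 UMIs, with medians of 3448 and 2976 UMIs per nucleus. The 18-month libraries totalled 63073988, 70896967 and 57299421 UMIs, with medians of 3338, 3445 and 3485 UMIs per nucleus. After filtering, 37053 nuclei were grouped into cell classes by fixed marker genes. Values are means ± SD over libraries, with n = 2 for the 17-month animal, n = 3 for the 18-month animal and n = 5 where both are pooled. The 5 libraries come from 2 animals, so p-values of cell type comparisons measure the spread between libraries and not between animals. Gene levels are in CPM of the summed UMIs of a class, and log2 fold changes carry their standard error (SE). Genes are given by symbol; the feature tables pair symbols with macaque Ensembl identifiers and hold no genome coordinates. The genes with the highest fold change in the comparisons of cell types were FSHR (ENSMMUG00000017196) in 2 of them, MORN5 (ENSMMUG00000059107), PLA2G5 (ENSMMUG00000064805), GALNT5 (ENSMMUG00000017717), SUSD5 (ENSMMUG00000007627) and LCP2 (ENSMMUG00000014126), by the rule for named genes.

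The first question was which cell types the tissue samples held, the series title naming a molecular taxonomy as its subject. Oligodendrocytes, the myelin-forming glia, were the most abundant class by the mean of each animal, with 39.8% ± 16.9 of nuclei in the 17-month animal (n = 2) and 38.5% ± 2.84 in the 18-month animal (n = 3). In 17-month library 1 they were 27.9% of nuclei, beside 28.0% excitatory neurons, and in library 2 they were 51.7%. Excitatory neurons made up 25.01% ± 4.23 and 22.8% ± 2.32, and inhibitory neurons 7.92% ± 3.17 and 6.96% ± 1.43. Striatal projection neurons, recognised by PDE10A, RGS9 and related markers, made up 2.52% ± 0.870 of nuclei in the 17-month animal and 8.08% ± 2.88 in the 18-month animal. Their library shares, with exact Clopper-Pearson 95% intervals, were 3.14% (2.75 to 3.56) and 1.91% (1.61 to 2.25) in the 17-month animal, and 4.75% (4.28 to 5.26), 9.82% (9.20 to 10.5) and 9.66% (8.93 to 10.4) in the 18-month animal. Microglia made up 7.67% ± 1.35 and 7.73% ± 1.14, oligodendrocyte precursors 5.11% ± 0.861 and 5.93% ± 1.18, astrocytes 3.97% ± 2.29 and 2.62% ± 0.515, and endothelial cells 1.68% ± 1.05 and 0.947% ± 0.319. The endothelial share of the 17-month animal spanned 2.43% (2.09 to 2.80) and 0.939% (0.732 to 1.19) in its libraries. The astrocyte share of the 17-month animal spanned 5.59% (5.08 to 6.14) and 2.36% (2.02 to 2.73) in its libraries. Committed oligodendrocyte precursors, with 197 nuclei, and mural cells or fibroblasts, with 148 nuclei, were the smallest named classes. No name was given to 2021 nuclei, of which 1939 formed a cluster with a median of 990 UMIs and mixed markers. There were 3.32 ± 0.793 excitatory nuclei per inhibitory nucleus in the 17-month animal and 3.31 ± 0.318 in the 18-month animal.

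Among 8785 excitatory nuclei, 5204 formed 4 clusters that carried claustrum markers (NR4A2, GNB4, SYNPR, NTNG2, SMYD1 and others) and are called claustrum-like here. They made up 57.3% ± 1.92 of excitatory nuclei in the 17-month animal (n = 2) and 60.6% ± 4.28 in the 18-month animal (n = 3). The share of claustrum markers on was 1.0 in excitatory clusters 1, 3 and 4 and 0.83 in cluster 5. Among their top 10 genes, clusters 1, 3 and 4 each held 1 claustrum marker and 1 marker of another class, CUX2. Excitatory cluster 5, with 691 nuclei and a score of 0.71, held 0 claustrum markers there. Nuclei with markers of cortical layers were less frequent: 617 were layer 6 corticothalamic (CT)-like, 323 layer 4/5 intratelencephalic (IT)-like and 190 layer 6b-like. The layer 4/5 IT-like nuclei were uneven, with 43 and 98 in the 17-month libraries and 21, 142 and 19 in the 18-month libraries. The remaining excitatory clusters, with 2451 nuclei, were left unnamed. Clusters 2 and 6 scored best as layer 5/6 near-projecting (NP)-like (0.72 and 1.0), with the next class at -0.05 and 0.06. Scores are scaled to the highest cluster of a class with at least 50 nuclei, so the 1.0 of cluster 6 was set by construction. Clusters 2 and 6 stayed unnamed because 60% of these markers were on, where more than 60% was needed. This limit, set after clusters had been seen, kept their 1514 and 656 nuclei out of the named reference for claustrum-like neurons. Cluster 11 had a score and a share below the limits, cluster 10 (146 nuclei) had low UMIs and cluster 12 had 18 nuclei. The unnamed clusters made up 29.6% ± 3.26 and 26.7% ± 1.87 of excitatory nuclei. Inhibitory nuclei held 815 nuclei that scored as VIP-type and 293 LAMP5 or SNCG-type nuclei, which carry markers of the caudal ganglionic eminence (CGE), and 575 PVALB-type and 334 SST-type nuclei, which carry markers of the medial ganglionic eminence (MGE). Of the 815 nuclei, 59 formed a cluster whose top 10 genes held 1 VIP-type marker and 2 markers of the LAMP5 or SNCG type (RELN and NDNF), so its VIP name is not supported by its top genes and 756 nuclei remain VIP-type. Of the 575 PVALB-type nuclei, 84 formed cluster 11, with a score of 0.53, near the limit, and 0 PVALB-type markers among its top 10 genes. Inhibitory cluster 1, with 398 nuclei, also had 0 there. Its score of 1.0 only marks it as the highest-scoring PVALB-type cluster, to which the others were scaled. Another 713 inhibitory nuclei stayed unnamed. Shares of animals were not tested, since an exact two-sided permutation test of 2 against 3 libraries has 10 splits and cannot give a p below 0.1. Intervals cover counting error only.

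**Figure D1:**
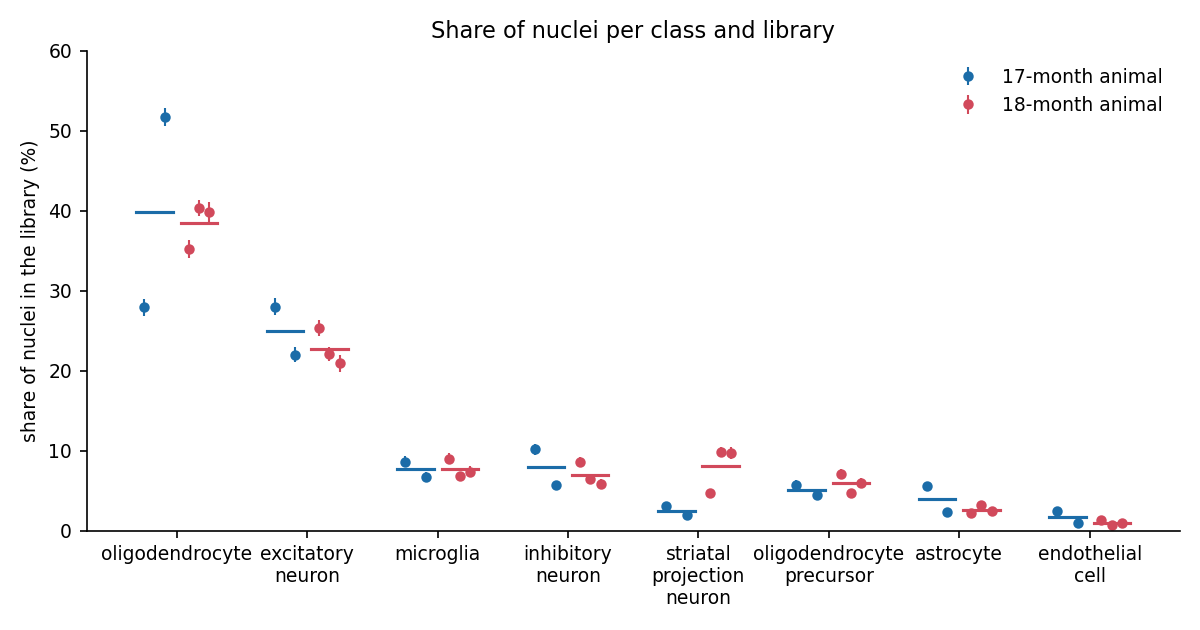
Share of nuclei (percent of all kept nuclei of a library) of each cell class, with a point and its exact 95% interval for each of the 5 libraries, coloured by animal, and a bar at each animal's mean. Striatal projection neurons sat between 1.91% and 3.14% in the 17-month libraries and between 4.75% and 9.82% in the 18-month libraries.

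Excitatory and inhibitory neurons were compared within libraries to describe the main neuronal division. Of the excitatory nuclei, 59.2% were claustrum-like, so some of the differences below depend on that type. As examples, FSHR (2.25 CPM), IL19 (0.822 CPM), TSPAN18 (9.62 CPM) and DRD2 (4.90 CPM) were low in the other named excitatory neurons. CACNA1A was at 25.5 CPM in claustrum-like and 759 CPM in other named excitatory neurons. FSHR, the receptor of follicle-stimulating hormone, had the highest fold change towards excitatory neurons, with 94.6 ± 47.9 CPM against 2.51 ± 1.34 CPM (n = 5; log2 5.16, SE 0.195, adjusted p = 1.79e-07 by edgeR). PDE4C, a cAMP phosphodiesterase (log2 4.72), ITPKA, an inositol trisphosphate kinase (log2 4.68), the cytokine IL19 (log2 4.60), the metalloprotease ADAMTS16 (log2 4.58), the Nogo receptor family member RTN4RL2 (log2 4.51) and the melanin-concentrating hormone receptor MCHR2 (log2 4.36) were also higher in excitatory neurons. MYO5C, TSPAN18 and FAP completed the 10 highest. Inhibitory neurons were higher in ADAM33 (log2 -7.64), the chloride channel ANO1 (log2 -6.95), TOX2 (log2 -6.71), the neuropeptide FF receptor NPFFR1 (log2 -6.22) and the growth factor IGF1 (log2 -6.02). In all, 2298 of 13665 genes tested were called, 1209 higher and 1089 lower in excitatory neurons, at an adjusted p under 0.05 and an absolute log2 fold change of at least 1.

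By list, of 11 measured neuropeptide genes, 6 were called lower and 1 higher in excitatory neurons, the lower ones including CRH (log2 -6.12), its binding protein CRHBP (log2 -5.58), PNOC, the precursor of nociceptin (log2 -5.34), and TAC3, the precursor of neurokinin B (log2 -3.93). As a set the neuropeptides were lower by camera (adjusted p = 0.00889), with adjusted p = 0.219 with an estimated correlation. Of 8 acetylcholine receptor genes, 4 were lower and 0 higher, namely the nicotinic subunits CHRNA2 (log2 -7.03), CHRNA6 (log2 -4.11), CHRNB3 (log2 -4.10) and CHRNA7 (log2 -1.44), and the set test gave adjusted p = 0.0931. Peptide receptors went both ways, with 7 of 17 higher and 5 lower. VIPR1, a receptor of vasoactive intestinal peptide, was higher (log2 4.15), and the substance P receptor TACR1 was lower (log2 -5.54). Of 37 potassium and HCN channel genes, 8 were higher, among them KCNV1 (log2 3.59) and KCNIP4 (log2 2.87), and 6 lower, among them KCNIP1 (log2 -3.81) and KCNAB1 (log2 -2.60). Of 22 sodium and calcium channel genes, 5 were higher, including the T-type subunit CACNA1H (log2 4.85) and the R-type subunit CACNA1E (log2 1.76), and 2 lower, CACNA2D2 (log2 -4.37) and the P/Q-type subunit CACNA1A (log2 -1.47). Of 24 glutamate receptor genes, 6 were lower, including the kainate subunit GRIK1 (log2 -3.75) and GRIN2D (log2 -2.28), and 1 higher, GRM2 (log2 2.53). GABA receptor genes had 1 of 13 higher, GABRA5 (log2 2.57), and 1 lower, GABRB2 (log2 -1.13). Of 8 catecholamine receptor genes, 3 were higher and 2 lower, with DRD2 (log2 2.98) and ADRA1B (log2 1.59) higher and ADRA1A (log2 -2.55) lower. Of 10 serotonin receptor genes, 4 were higher, with HTR6 (log2 1.67) and HTR1A (log2 1.59) first, and 2 lower, HTR2C and HTR3A (log2 -3.18 in the latter). Calcium-binding proteins had 1 of 15 higher, CABP1 (log2 1.71), and 4 lower, led by SCGN (log2 -6.10).

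Of 49 axon guidance and cadherin genes, 14 were higher, among them SLIT3 (log2 3.73) and PLXND1 (log2 3.69), and 15 lower, among them NTN4 (log2 -5.20) and NRP2 (log2 -3.40). Of 6 genes that rodent reports place in the claustrum, 4 were called higher in excitatory neurons: LXN (log2 1.99), NNAT (log2 1.52), SMIM32 (log2 1.33) and GNG2 (log2 1.00). This set was higher by camera (adjusted p = 0.0154), with adjusted p = 0.219 with an estimated correlation. Apart from the neuropeptides and this set, no list passed camera at its preset correlation. Adjusted over the list alone, the counts of all 12 lists were those given. For the serotonin receptors the median and mean log2 fold change were -0.13 and -0.17 while the set test pointed up, and for the peptide receptors the median was 0.37 and the mean -0.18. GNG2 sat at the fold threshold, and its log2 value fell to 0.98 without 18-month library 1, 1.00 without library 2 and 0.97 without library 3, with 0.93 at the lowest, for at least 1000 genes per nucleus. NNAT missed the p threshold without 18-month library 1 (adjusted p = 0.0501) and library 2 (adjusted p = 0.0553).

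Claustrum-like neurons were compared with the other named excitatory neurons to describe what set them apart from cortical layer types of the same libraries. FSHR was highest again, at 147 ± 70.9 CPM in claustrum-like neurons against 2.25 ± 1.04 CPM (n = 5; log2 5.95, SE 0.228, adjusted p = 9.05e-07 by edgeR). It was higher in 5 of 5 libraries, which the rule for named genes required. Its level in claustrum-like neurons was 78.8 and 72.6 CPM in the 17-month libraries and 157, 194 and 235 CPM in the 18-month libraries, without overlap. IL19 followed at 34.3 ± 6.01 against 0.822 ± 0.652 CPM (log2 5.61, SE 0.266), then the membrane scaffold syntrophin SNTB1 at 219 ± 25.9 against 7.05 ± 2.55 CPM (log2 4.90, SE 0.129). TSPAN18 (log2 4.53), JHY (log2 4.34), the sodium, calcium and potassium exchanger SLC24A4 (log2 4.32), the lipase LIPG (log2 4.25), the kappa opioid receptor OPRK1 (log2 4.14), the cation channel TRPC7 (log2 4.10) and the G protein regulator RGS12 were also higher. The other excitatory neurons were higher in CRHR2, a receptor of corticotropin-releasing hormone (22.8 ± 12.3 against 0.120 ± 0.0448 CPM, log2 -7.53), IQCF2 (log2 -6.29), FRMPD2 (log2 -6.23), the heparan sulfate sulfotransferase HS3ST3B1 (log2 -5.94), ARSJ (log2 -5.78), FSTL5 (log2 -5.67), the transcription factor TOX (log2 -5.26), the neurokinin receptor TACR3 (log2 -5.26) and the growth factor BMP5 (log2 -5.10). In all, 1228 of 11959 genes were called, 518 higher and 710 lower.

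**Figure D2:**
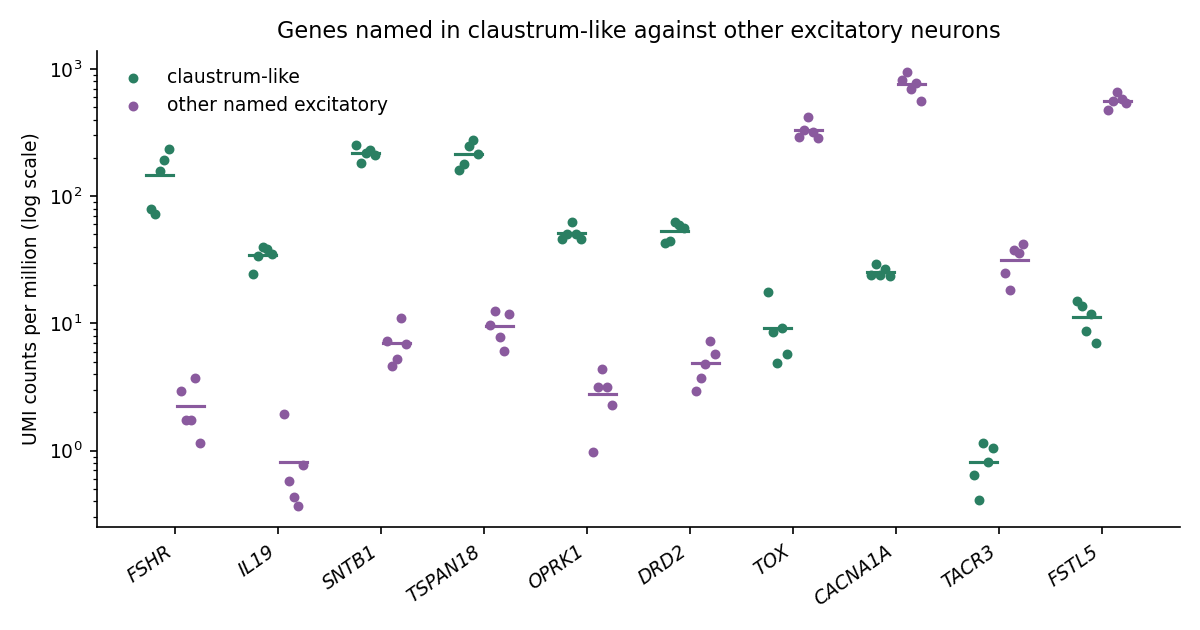
Level (CPM, log axis) of genes with large differences in claustrum-like and in other named excitatory neurons, with a point for each of the 5 libraries and a line at the mean. FSHR averaged 147 CPM in claustrum-like neurons and 2.25 CPM in the other excitatory neurons, and CACNA1A 25.5 and 759 CPM.

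Of 49 axon guidance and cadherin genes, 19 were lower and 5 higher in claustrum-like neurons, the lower ones including SEMA3A (log2 -4.84), CDH22 (log2 -3.79), ROBO3 (log2 -3.71) and SEMA5A (log2 -3.27). The set was lower by camera (adjusted p = 0.00125), with adjusted p = 0.328 with an estimated correlation. No other list passed camera in this comparison. CACNA1A, the pore subunit of P/Q-type calcium channels, was at 25.5 ± 2.50 CPM in claustrum-like and 759 ± 143 CPM in other excitatory neurons (log2 -4.88, SE 0.0813). CACNA2D2 was lower too (log2 -3.59), and CACNA1H higher (log2 1.51), the other 19 of 22 sodium and calcium channel genes not being called. Of 24 glutamate receptor genes, 6 were lower, led by the metabotropic receptors GRM3 (log2 -4.69) and GRM4 (log2 -3.91) and the kainate subunits GRIK4 (log2 -3.26) and GRIK3 (log2 -3.14), and 3 higher. Potassium and HCN channel genes had 7 of 37 higher, including KCNV1 (log2 2.77), and 9 lower, including KCNK1 (log2 -2.84) and KCNB2 (log2 -2.44). Among catecholamine receptors, the dopamine receptor DRD2 (log2 3.38, 53.2 ± 8.88 against 4.90 ± 1.69 CPM) and ADRA1B (log2 1.52) were higher, and ADRB1 was lower (log2 -3.18). Of 16 peptide receptor genes, 2 were higher, OPRK1 being the first, and 4 lower, including the mu opioid receptor OPRM1 (log2 -4.05). GALR1 had 15 counts in other excitatory and 2 in claustrum-like neurons, a ratio of 43.4 with a 95% counting interval of 10.1 to 391. Neuropeptide genes had 3 of 8 lower, ADCYAP1 (log2 -3.98), GRP (log2 -3.57) and PDYN (log2 -2.89), and 1 higher, NPY. Serotonin receptors had 2 of 10 lower, with HTR4 first (log2 -3.06), and 0 higher. GABA receptors had GABRA5 higher (log2 1.65) and GABRA3 (log2 -1.43) and GABRG1 (log2 -2.13) lower of 13. Calcium-binding proteins had 2 of 15 lower, SCGN (log2 -3.41) and NCALD (log2 -2.21), and acetylcholine receptors 3 of 6 lower. Of the 6 claustrum genes of rodent reports, LXN (log2 2.52), SMIM32 (log2 2.07) and GNG2 (log2 1.56) were higher and the zinc transporter SLC30A3 lower (log2 -3.12).

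Adjusted over the list alone, the lower counts in claustrum-like neurons rose to 3 serotonin receptors, 4 neuropeptides, 11 potassium and HCN channels and 20 axon guidance genes, and the others stayed. For serotonin receptors the median log2 fold change was 0.53, the mean -0.60 and the set test up, and for sodium and calcium channels the median was 0.14, the mean -0.16 and the set test up. Against the unnamed excitatory clusters, an alternative chosen after the data were seen, DRD2 (log2 0.59), TRPC7 (log2 0.38), CACNA1H (log2 0.23), ROBO3 (log2 -0.49), GRM4 (log2 -0.98) and GABRG1 (log2 -0.40) were no longer called. Against all other excitatory nuclei, DRD2 (log2 0.98), TRPC7 (log2 0.81) and CACNA1H (log2 0.49) were not called. Against layer 4/5 IT-like nuclei alone, BMP5 turned to log2 2.57 (adjusted p = 0.115), and GRM4 (log2 -0.75), GABRA3 (log2 -0.32), NPY (log2 0.71) and GRIK3 (adjusted p = 0.0566) were not called. Against layer 6b-like nuclei alone, GABRA5 (log2 0.70), GABRA3 (log2 -0.65), ADRA1B (log2 0.72), GRM4 (log2 -0.78), SEMA5A (adjusted p = 0.0898) and BMP5 (adjusted p = 0.118) were not called. Against layer 6 CT-like nuclei alone, SLC30A3 was at log2 -0.10 and GABRG1 at log2 -1.21 (adjusted p = 0.208). GABRG1 was not called in sums per animal (log2 -1.996, adjusted p = 0.0609) either, nor NPY after background subtraction, where its log2 value rose from 1.08 to 2.46 (adjusted p = 0.0978). NPY was not called without 18-month library 2 (log2 0.97) or library 3 (log2 0.99).

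MGE-like inhibitory neurons (PVALB and SST types) were compared with CGE-like ones (VIP, LAMP5 and SNCG types), the main division of forebrain interneurons. MGE-like neurons were higher in MORN5 at 54.4 ± 10.9 against 0.627 ± 0.589 CPM (n = 5; log2 6.31, SE 0.286, adjusted p = 1.37e-19), SH3RF2 (log2 4.67), the kainate receptor subunit GRIK3 (412 ± 15.1 against 19.96 ± 4.37 CPM, log2 4.35), LRIG3 (log2 4.24), the urea cycle enzyme CPS1 (log2 4.09), the heparan sulfate proteoglycan GPC6 (log2 3.98), STXBP6, SHROOM3 and CRHBP (each log2 3.74 to 3.76). The kinase TEC had 329 counts in MGE-like and 3 in CGE-like neurons, a ratio of 90.2 with a 95% counting interval of 30.6 to 440. CGE-like neurons were higher in the nicotinic subunit CHRNA2, with 192 counts against 0, which makes it at least 77.8-fold higher against a floor of 3 counts over the class. Secretagogin, SCGN, a calcium sensor, had 320 counts against 2 (ratio 194, interval 53.4 to 1612), and the natriuretic peptide receptor NPR3 had 196 against 1 (ratio 238, interval 42.3 to 9456). CRISPLD1 (log2 -5.33), PLPP4 (log2 -4.99), the protocadherin FAT4 (log2 -4.67), FBN3 (log2 -4.67), CHRDL1 (log2 -4.62), COBL (log2 -4.50) and LRRC3B (log2 -4.40) were also higher in CGE-like neurons. In all, 764 of 9177 genes were called, 364 higher and 400 lower in MGE-like neurons.

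By list, acetylcholine receptors had 3 of 5 lower and 0 higher in MGE-like neurons, the third besides CHRNA2 and CHRNA6 being CHRNB3 (log2 -3.94). CHRNA6 had 49 counts in CGE-like and 1 in MGE-like neurons, a ratio of 59.6 (interval 10.2 to 2399). The set was lower by camera (adjusted p = 0.000816), with adjusted p = 0.101 with an estimated correlation. Catecholamine receptors had 4 of 5 lower, ADRA1B (log2 -2.19), ADRA1D (log2 -2.13), ADRB1 (log2 -1.32) and ADRA1A (log2 -1.05), and the set was lower (adjusted p = 0.00474), with adjusted p = 0.169 with an estimated correlation. Of 14 calcium-binding protein genes, 6 were lower, including NECAB2 (log2 -3.91) and HPCAL1 (log2 -2.78), and 1 higher, and the set was lower (adjusted p = 0.00121), with adjusted p = 0.101 with an estimated correlation. No other list passed camera here. Peptide receptors had 4 of 10 higher, including CCKBR (log2 2.54) and OPRM1 (log2 2.53), and 5 lower, including the orexin receptor HCRTR2 (log2 -3.62) and the cannabinoid receptor CNR1 (log2 -3.04). Neuropeptides had 2 of 8 higher, CRHBP first (log2 3.74), and 4 lower, including CRH (log2 -4.52), TAC3 (log2 -3.81) and cholecystokinin, CCK (log2 -3.30). Potassium and HCN channels had 10 of 32 lower, led by KCNB2 (log2 -2.31), and 1 higher. Sodium and calcium channels had 4 of 21 higher, including CACNA2D2 (log2 2.21), and 3 lower, including CACNA1I (log2 -2.35). Glutamate receptors had 3 of 23 higher, with GRIK3 and GRIA3 (log2 1.64), and 2 lower, GRIN2A (log2 -2.13) and GRM7 (log2 -1.90). HTR7 was the called serotonin receptor of 6 (log2 3.44), and GABRG1 (log2 -1.50) and GABRA5 (log2 -1.20) the called GABA receptors of 13. Axon guidance genes had 5 of 47 higher and 17 lower, led by CDH6 (log2 -3.65). Of 5 measured claustrum genes of rodent reports, SLC30A3 was higher (log2 2.90) and GFRA1 lower (log2 -1.33). Adjusted over the list alone, 1 serotonin receptor and 18 axon guidance genes were lower, and the other counts stayed. For glutamate receptors the median log2 fold change was -0.0049, the mean 0.09 and the set test up, and for the rodent claustrum genes the median was -0.15, the mean 0.21 and the set test down. GFRA1 was not called without 17-month library 1 (log2 -0.98), nor ADRA1A without 18-month library 2 (log2 -0.98) or without the CGE-like cluster of mixed top genes (log2 -0.96), an alternative chosen after the data were seen that called 760 genes. ADRB1 was not called by DESeq2 (adjusted p = 0.0646), and GPC6 was not called in sums per animal (log2 3.84, adjusted p = 0.190).

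The 4 glial classes were each compared with the mean of the other 3 on the log scale to describe the non-neuronal part of the taxonomy. A gene raised in 1 class raises the mean that the others are set against, so its lower values in those classes are not separate results. Astrocytes had their highest folds in the phospholipase PLA2G5 (37.2 ± 7.37 CPM, n = 5, log2 8.73, SE 0.407), the retinoid isomerase RPE65 (log2 8.26), the cadherin family member CDHR3 (log2 8.15), LMNTD1 (log2 7.65) and CYP4F8 (log2 7.49). Of 12 ion and transmitter uptake genes, 8 were higher in astrocytes and 1 lower, including SLC7A10 (log2 4.81), the sodium pump subunit ATP1B2 (log2 3.67) and the GABA transporter SLC6A11 (log2 3.09). The set was higher by camera at its preset correlation (adjusted p = 0.000537) and with an estimated one (adjusted p = 0.0288). GABA receptors had 4 of 13 higher in astrocytes, including GABRG1 (log2 4.88), GABBR1 (log2 3.23) and GABRA2 (log2 2.33), and 1 lower. Glutamate receptors had GRM3 (log2 2.55) and GRIN2C (log2 2.12) higher and 8 of 22 lower, with GRIK1 (log2 -1.78) and GRIK2 (log2 -1.65). Astrocytes had 2132 of 10357 genes called, 1288 higher and 844 lower.

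Oligodendrocytes were higher in GALNT5 (37.9 ± 21.4 CPM, log2 7.71, SE 0.276), NIPAL4 (log2 6.57), C9H10orf90 (868 ± 87.0 CPM, log2 5.85), ACP7 (log2 5.60) and SMIM2 (log2 5.41). Of 13 myelin lipid and cholesterol genes, 6 were higher and 0 lower in oligodendrocytes, including the fatty acid hydroxylase FA2H (log2 4.59), aspartoacylase ASPA (log2 4.25), the galactolipid enzyme UGT8 (log2 3.61) and the lipid transporter ABCA2 (log2 3.17). The set was higher (adjusted p = 0.00492), with adjusted p = 0.295 with an estimated correlation. The glycine transporter SLC6A9 was higher (log2 3.76), as was the metabotropic receptor GRM3 (log2 3.34). Oligodendrocytes had 2068 genes called, 782 higher and 1286 lower.

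Oligodendrocyte precursors were higher in SUSD5 (145 ± 11.4 CPM, log2 7.43, SE 0.186), BTNL9 (log2 7.03), SPSB4 (log2 6.67), the acid-sensing channel ASIC4 (log2 6.45) and the transcription factor CREB3L1 (log2 6.20). Of 22 glutamate receptor genes, 15 were higher in precursors and 1 lower, among them GRIK1 (log2 3.61), GRIK3 (log2 3.34) and GRIN2D (log2 3.10). The set was higher by camera (adjusted p = 1.63e-08), with adjusted p = 0.0971 with an estimated correlation. The potassium channel KCNJ16 (log2 6.18) and the GABA receptor subunit GABRA3 (log2 2.33) were higher, and the glutamine synthetase gene GLUL was lower (log2 -2.27). Precursors had 1855 genes called, 1092 higher and 763 lower.

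Microglia, the resident immune cells, were higher in LCP2 (361 ± 28.0 CPM, log2 9.46, SE 0.173), LY86 (log2 8.54), CD48 (log2 8.40), NCKAP1L (log2 8.23) and the cytokine IL1B (log2 8.15). All 13 immune and complement genes were called higher in microglia, including SYK (log2 7.98), ITGAM (log2 7.41) and TREM2 (log2 5.86), and the set was higher at the preset correlation (adjusted p = 1.86e-10) and with an estimated one (adjusted p = 0.00454). Because microglia are in the mean that the other classes were set against, the list also came out lower there, at least in part by construction, with 9 of 13 called in astrocytes, 8 in oligodendrocytes and 11 in precursors, where the set tests gave adjusted p = 0.0176, 0.00346 and 0.000407, and 0.236, 0.202 and 0.0971 with an estimated correlation. Ion and transmitter uptake genes had 8 of 12 lower in microglia, including KCNJ10 (log2 -2.83), with adjusted p = 0.00127, and 0.0429 with an estimated correlation. Glutamate receptors had 9 of 22 lower, led by GRIK4 (log2 -3.33) and GRM3 (log2 -2.98), with adjusted p = 0.000111, and 0.193 with an estimated correlation. Myelin lipid and cholesterol genes had 5 of 13 lower, led by FA2H (log2 -3.21), with adjusted p = 0.0324, and 0.311 with an estimated correlation. Microglia had 2684 genes called, 1153 higher and 1531 lower. The other list tests in the glial classes did not pass camera. Adjusted over the list alone, the counts of the glial lists were those given. Medians and means differed in sign for myelin genes (0.05 and -0.41) and GABA receptors (-0.58 and 0.46) in astrocytes, where both set tests pointed down, and for GABA receptors in microglia (0.22 and -0.34, set test down).

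LY86 had 2 counts in astrocytes and 2 in precursors against 1153 in the other classes, ratios of 53.2 (95% counting interval 14.7 to 440) and 95.2 (26.3 to 787). SLC7A10 and KCNJ16 each had 3 counts in microglia, ratios of 11.3 (3.82 to 55.0) and 16.0 (5.42 to 77.7) in the other classes' favour. The lower value of LY86 in oligodendrocytes was not called without 17-month library 1 (log2 -1.13) or library 2 (log2 -1.77), in precursors without 17-month library 1 (log2 -2.17), and in astrocytes without 18-month library 1 (log2 -2.41). In sums thinned to the smallest total, LY86 in oligodendrocytes (adjusted p = 0.433) and KCNJ16 in microglia (adjusted p = 0.183) were not called. After background subtraction LY86 was not called in astrocytes (log2 -4.82), oligodendrocytes (log2 -1.42, adjusted p = 0.804) or precursors (log2 -4.78). SLC17A7, a marker of excitatory neurons, was at 85.3 ± 6.48 CPM in excitatory neurons and 47.8 ± 12.4 CPM in oligodendrocytes. In the other neuron and glial classes it ranged from 10.4 ± 3.75 CPM in striatal projection neurons to 51.9 ± 17.8 CPM in microglia. These counts may be RNA of other cells.

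The libraries of the 18-month animal were compared with those of the 17-month animal in 8 classes; the labels state no question for this comparison. ANKRD30A was higher in the 18-month animal in excitatory neurons, at 126 ± 14.2 CPM (n = 3) against 19.2 ± 4.02 CPM (n = 2; log2 2.71, SE 0.162, adjusted p = 0.00112 by edgeR), and in inhibitory neurons (log2 2.37). OVGP1, an oviductal glycoprotein, was lower in all 8 classes (log2 -1.96 to -0.54) and called in 7, with 12.5 ± 0.625 against 45.2 ± 0.856 CPM in excitatory neurons (log2 -1.85). GLT8D2, a glycosyltransferase family gene, was higher in excitatory (log2 1.77) and striatal projection neurons (log2 2.30). The phosphodiesterase PDE3A (log2 -4.14), the dynein gene DNAH8 (log2 -3.19) and the laminin gene LAMA3 (log2 -2.37) were lower in excitatory neurons, and the zinc finger gene ZNF43 (log2 2.22) and HMCN1 (log2 1.86) higher. ZNF43 was called in 6 classes and had a positive log2 value in 7 of 8.

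In striatal projection neurons PDZD9 (log2 2.83) and CECR2 (log2 2.41) were higher, and DNAH8 (log2 -4.50) and the innate immune receptor TLR4 (log2 -2.78) lower. In oligodendrocytes COL18A1 (log2 3.37), CNTLN (log2 3.20) and PRUNE2 (log2 2.70) were higher, and the synaptic scaffold SHANK3 (3.77 ± 0.885 against 128 ± 11.2 CPM, log2 -5.05), the growth factor FGF1 (log2 -3.04) and SYT16 (log2 -2.80) lower. ZNF257 was higher in all 8 classes (log2 1.01 to 2.36) and called in 6. In precursors ZNF257 (log2 2.26) and the potassium channel KCNH5 (log2 1.95) were higher, and ARHGAP15 (log2 -3.69) and the cold-sensing channel TRPM8 (log2 -3.24) lower. In microglia ENPP1 (log2 3.20), IGF2BP2 (log2 2.95), HMGA2 (log2 2.33) and LYVE1 (log2 2.28) were higher, and CMTM8 (log2 -5.07), LILRA1 (log2 -4.74) and ABCA4 (log2 -4.71) lower. Astrocytes were higher in SYT2 (log2 2.69) and WDR49 (log2 2.36). Endothelial nuclei were higher in ASPN (log2 3.69) and OGN (log2 2.64) and lower in MYH11 (log2 -3.21) and THSD4 (log2 -2.71), 4 genes to which DESeq2 gave no adjusted p. ASPN and OGN are known from fibroblasts and MYH11 from mural cells, so genes of other vascular cells were among those called in the endothelial class.

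FKBP5, a co-chaperone of steroid receptors, was singled out after its values were seen: its log2 value was negative in all 8 classes and it was called in 7, with 372 CPM in the 17-month and 152 CPM in the 18-month animal in astrocytes (log2 -1.27, SE 0.127). The values were -2.27 in oligodendrocytes, -1.71 in endothelial cells, -1.53 in striatal projection neurons, -1.14 in precursors, -0.84 in excitatory neurons and -0.62 in inhibitory neurons, while microglia had -0.32 with adjusted p = 0.0723. It was not alone in this: of 6932 genes tested in all classes, 8 were called in 7 classes, 5 of them in the same direction in all 8, and 28 were called in at least 6. FKBP5 was called in astrocytes, oligodendrocytes, precursors and endothelial cells under every alternative tried, including each library left out. In excitatory neurons it was not called without 17-month library 1 (log2 -0.89) or library 2 (log2 -0.78), and in inhibitory neurons not without 17-month library 1 (log2 -0.58) or by DESeq2 (adjusted p = 0.135). In striatal projection neurons it was not called without 18-month library 1 (log2 -1.53), 2 (log2 -1.49) or 3 (adjusted p = 0.114), or with no filter on low counts (adjusted p = 0.061), and it was at log2 -0.93 without 17-month library 2. After background subtraction, chosen after the data were seen, it was not called in inhibitory neurons (log2 -0.16, adjusted p = 0.692) or striatal projection neurons (adjusted p = 0.129).

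**Figure D3:**
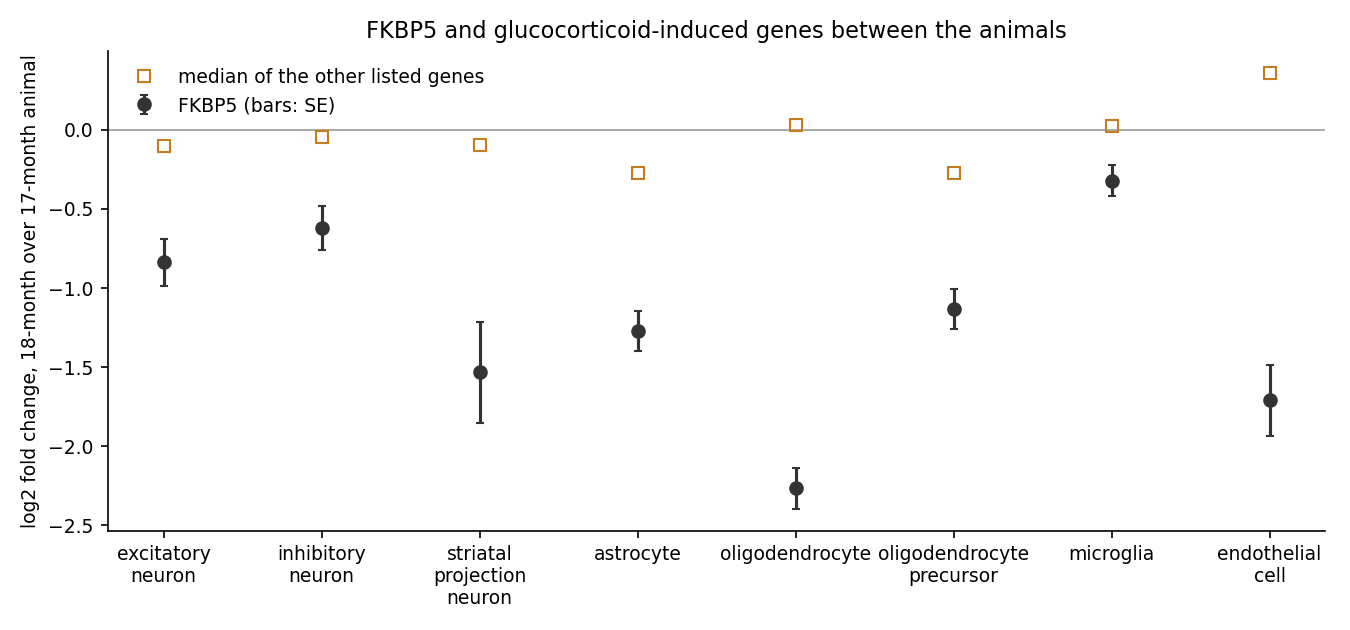
Log2 fold change of FKBP5 between the animals in each cell class (points, bars for SE) and the median of other glucocorticoid-induced genes (open squares). FKBP5 ranged from -2.27 in oligodendrocytes to -0.32 in microglia, and the medians from -0.28 to 0.36.

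Heat shock and stress genes were called higher 18 times over the 8 classes and lower 0 times. In endothelial cells 5 of 6 measured members were called, including HSP90AA1 (619 ± 45.6 against 286 ± 48.3 CPM, log2 1.11) and HSPA8 (log2 0.90). HSPA8 was not called there without 17-month library 2 (log2 0.64) or without 18-month library 1 (log2 0.85) or 3 (log2 0.85). Camera called the set higher in inhibitory neurons (adjusted p = 0.00105), striatal projection neurons (0.0124), oligodendrocytes (0.00247), precursors (0.00997), microglia (0.0158) and endothelial cells (8.05e-07). With an estimated correlation the adjusted p values were 0.106, 0.403, 0.669, 0.623, 0.497 and 0.207. The members called higher numbered 12 without 17-month library 1, 1 without 17-month library 2, 6 without 18-month library 1, 21 without library 2 and 9 without library 3. After background subtraction they numbered 15, with 0 instead of 2 in excitatory neurons, where the median log2 fold change of the list fell from 0.19 to 0.06, while the median of the 8 class medians rose from 0.36 to 0.65. In the low-UMI cluster HSP90AA1 was at 739 ± 224 CPM and HSPA8 at 298 ± 101 CPM, against 94.8 ± 8.07 and 36.2 ± 4.40 CPM in excitatory neurons (n = 5). Activity-regulated genes were higher by camera in inhibitory neurons (adjusted p = 0.0409) and striatal projection neurons (0.0181), with adjusted p = 0.339 and 0.403 with an estimated correlation. The immediate early gene FOS was higher in inhibitory neurons (log2 1.49), NR4A1 in striatal projection neurons (log2 1.06), and HOMER1 in excitatory (log2 0.94) and striatal projection neurons (log2 1.09). The mitochondrial set passed in no class by camera, and 1 member was called lower in each of excitatory neurons, inhibitory neurons and oligodendrocytes, in the last ND3 (log2 -2.23, 1.74 ± 0.524 against 8.66 ± 0.866 CPM). Adjusted over the list alone, heat shock genes had 5 called in inhibitory neurons instead of 3, 4 in oligodendrocytes instead of 3, and 2 instead of 1 in precursors and in microglia. Activity-regulated genes then had 3 higher and 1 lower in inhibitory neurons, and microglia 1 mitochondrial gene lower. Mitochondrial medians and means differed in sign in inhibitory neurons (0.23 and -0.35, set test down), oligodendrocytes (0.02 and -0.26, set test down) and precursors (0.17 and -0.12, set test up).

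The genes called were 2038 in excitatory neurons, 905 in inhibitory neurons, 1298 in striatal projection neurons, 601 in astrocytes, 1734 in oligodendrocytes, 573 in precursors, 572 in microglia and 329 in endothelial cells, with no fold threshold. Libraries of the animals did not overlap in 49.3% of excitatory genes and in 34.0% of astrocyte genes, the highest and lowest share of the classes, where chance gives 20%. Excitatory and inhibitory neurons shared 432 calls in the same direction, with 61.9 given by independent calls. For excitatory neurons and the other classes these were 438 and 89.8 with striatal projection neurons, 426 and 115 with oligodendrocytes, 125 and 41.8 with astrocytes, 124 and 39.8 with precursors, 112 and 37.3 with microglia and 40 and 21.1 with endothelial cells. Calls of excitatory neurons in the opposite direction numbered 12 with inhibitory and 29 with striatal projection neurons, 38 with oligodendrocytes and 20 with astrocytes. They numbered 26 with precursors, 24 with microglia and 15 with endothelial cells. All classes come from the same libraries, so shared calls are not independent evidence. These p-values measure only the spread between libraries of 1 animal each, so age, individual and handling of the tissue cannot be told apart. Without 17-month library 1 the counts were 186 in excitatory, 376 in inhibitory and 449 in striatal projection neurons, 324 in astrocytes, 654 in oligodendrocytes, 356 in precursors and 191 in microglia, and without library 2 of that animal 222, 416 and 635 in the neurons, 779 in oligodendrocytes and 253 in microglia. Without 18-month library 1 the counts were 938 in oligodendrocytes, 316 in precursors, 219 in microglia and 73 in endothelial cells, without library 2 1261 in microglia, and without library 3 311 in astrocytes, 974 in oligodendrocytes, 318 in precursors, 285 in microglia and 109 in endothelial cells.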

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

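The tests of 3 patterns and the splits of the sums were chosen after the results were seen, and the tests of interaction below were run on genes named by the fixed rule. For 15 named genes, GRM3 in 2 classes, the size of a cell type difference differed between the 2 animals by a test of the interaction in edgeR, given here on the log2 scale as the 18-month minus the 17-month difference. Between excitatory and inhibitory neurons these were NECAB2 (2.30), TSPAN18 (1.37), ADAMTS16 (1.12, adjusted p = 0.0243), ANKRD55 (1.02), the axon guidance gene SLIT3 (0.69) and the adrenergic receptor ADRA1B (0.53). The direction was the same in both animals for each of them: TSPAN18 had log2 ratios of mean CPM of 3.36 in the 17-month and 4.70 in the 18-month animal, and NECAB2 -2.73 and -0.92. In claustrum-like against other excitatory neurons, GABRG1 (-1.49) and NCALD (-0.65) differed, and in MGE-like against CGE-like neurons the proteoglycan GPC6 (1.796), with ratios of 3.04 and 4.83. In glia these were GRM3 (0.98) in astrocytes, C9H10orf90 (1.06) and FA2H (0.65) in oligodendrocytes, GRIK3 (0.78) and GRIK1 (0.90) in precursors, and GRM3 (-0.65) and GRIK4 (-1.30) in microglia. Glial interactions come from the fit on the log scale, so they need not equal differences of ratios of mean CPM. Over all genes tested, 153, 17 and 9 differed in the 3 neuron comparisons, and 264, 374, 153 and 388 in astrocytes, oligodendrocytes, precursors and microglia. With 1 animal per age, these differences cannot be assigned to age.

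The first pattern is the number of genes called between the animals, 8050 over the 8 classes, such as PDE3A in excitatory neurons and SHANK3 in oligodendrocytes. A difference in depth is argued against as the whole cause, since 6330 calls (78.6%) were still made in sums thinned to the smallest total. RNA from other cells stays open, because the profile of the low-UMI cluster that was subtracted is only assumed to be background. The share estimated by it was higher in each 17-month library than in each 18-month library in astrocytes (19.9% to 26% against 10.9% to 18.4%), microglia (22.6% to 26.3% against 17% to 20.7%), oligodendrocytes (19.7% to 21.8% against 13% to 18.8%), precursors (16.7% to 20.4% against 8.02% to 14.5%) and inhibitory neurons (9.44% to 9.56% against 3.87% to 6.46%). The libraries overlapped in excitatory neurons (3.70% and 4.58% against 3.22% to 9.44%), striatal projection neurons (4.46% and 9.23% against 3.01% to 5.04%) and endothelial cells (13.6% and 15.7% against 1.92% to 16%). After the subtraction 4396 calls (54.6%) were still made and 3654 ended. Of the calls that ended, the median absolute log2 fold change moved from 0.58 to 0.56 while their median SE rose from 0.14 to 0.18. Age cannot be told apart from the individual or from handling of the tissue with 1 animal per age, and variants of either animal that alter read counting were not tested. The mix of subtypes within a class was not held fixed in these tests. Layer 4/5 IT-like nuclei, for example, were 1.12% to 7.32% of excitatory nuclei over the libraries.

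The second pattern is the higher share of striatal projection neurons in the 18-month animal. The tissue taken into each library is a candidate explanation: within that animal the ratio of striatal to claustrum-like nuclei differed 2.74-fold between libraries, against 1.14-fold for inhibitory neurons. The value rests on 18-month library 1, without which the striatal ratio differed 1.05-fold. Named cortical nuclei varied 2.69-fold, and 1.35-fold without library 2, and a cluster marked by HTR2C and DRD3 had 167 of its 183 nuclei in 18-month library 2. In the 17-month animal the striatal ratio differed 1.23-fold, the inhibitory ratio 1.34-fold and the named cortical ratio 1.86-fold. RNA from other cells stays open. The median UMIs of striatal nuclei were at least 3.13 times that of their library, but this could not have come out otherwise. Named neuron clusters all had medians of 6147 UMIs or more, and the 2 oligodendrocyte clusters 2308 and 2908, so any named neuron class would pass. Age stays open, because an exact permutation test over the libraries gives no p below 0.1 and each age is 1 animal.

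The third pattern is FKBP5, lower in the 18-month animal in 8 of 8 classes and called in 7. It is 1 of 8 genes called in 7 classes, of which 5 had the same direction in all 8, OVGP1 among them. The neuronal calls were the less firm ones: FKBP5 was not called in excitatory neurons without 17-month library 1 (log2 -0.89) or 2 (log2 -0.78), in inhibitory neurons without 17-month library 1 (log2 -0.58), or in striatal projection neurons without 18-month library 1 (log2 -1.53), 2 (log2 -1.49) or 3 (adjusted p = 0.114), where it was at log2 -0.93 without 17-month library 2. In inhibitory neurons its log2 value was -0.16 after background subtraction, and RNA from other cells stays open there too. FKBP5 is induced by glucocorticoids, so lower receptor activity in that animal may be an explanation. Over the 8 to 11 members measured in a class, of 12 listed glucocorticoid-induced genes, camera gave a lowest adjusted p of 0.214 over the classes, and 0.656 with an estimated correlation. Over the 8 classes 7 values of members were called lower and 1 higher. The lower ones were ZBTB16 in striatal projection neurons, HIF3A in astrocytes, SGK1 in precursors, SGK1 and ZBTB16 in microglia and 2 of SGK1, ZBTB16 and ARRDC2 in oligodendrocytes, where the other one was higher. The test leaves the explanation open, along with age, the individual and handling of the tissue, which were not tested.

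In random splits of the sums, 1 of 100 splits, the real one, gave as many genes in each cell type comparison. The classes were formed by clustering counts of the same nuclei, so the real split was bound to give more genes, and the splits decide nothing on chance or on whether the classes exist. Excitatory against inhibitory neurons had 2298 genes and 0 in the highest other split, claustrum-like neurons 1228 and 1, and MGE-like against CGE-like neurons 764 and 2. Astrocytes had 2132 and 1524, oligodendrocytes 2068 and 670, precursors 1855 and 911, and microglia 2684 and 1439. The high values of other glial splits point to a structure of the sums that a random split can keep in part, which was not tested.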

How the results depend on the processing

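Background subtraction, the other references for claustrum-like neurons and the smaller CGE-like class were chosen after seeing the data, and the other alternatives before. Counts between cell types moved little and counts between animals moved often. By more than 1.5 times, 39 of 120 alternative counts between animals moved and 1 of 118 between cell types, claustrum-like against layer 4/5 IT-like nuclei alone (810). DESeq2 called 317 genes in inhibitory neurons, 229 in astrocytes, 186 in precursors, 257 in microglia and 127 in endothelial cells. Thinned sums gave 196 in endothelial cells. With replicate number as a block, 1325 were called in excitatory and 629 in striatal projection neurons, 361 in astrocytes, 514 in oligodendrocytes, 262 in precursors and 170 in microglia. After background subtraction, 1306 were called in excitatory and 573 in inhibitory neurons, 705 in oligodendrocytes, 313 in precursors and 191 in microglia. Leaving out 1 library gave 186 to 2475 in excitatory, 376 to 681 in inhibitory and 449 to 1119 in striatal projection neurons, 311 to 587 in astrocytes, 654 to 2158 in oligodendrocytes, 316 to 572 in precursors, 191 to 1261 in microglia and 73 to 422 in endothelial cells. For cell types it gave 2179 to 2278 for excitatory against inhibitory, 1099 to 1206 for claustrum-like and 707 to 745 for MGE-like neurons, 2018 to 2132 for astrocytes, 1937 to 2064 for oligodendrocytes, 1735 to 1856 for precursors and 2555 to 2718 for microglia. BMP5 reversed to log2 2.57 against layer 4/5 IT-like nuclei alone. With at least 1000 genes per nucleus, the claustrum-like share of the 17-month animal was 54.9% and the excitatory share of the 18-month animal 25.6%. Of shares, 27 of 282 values moved by 1 SD over libraries or more. Values with 1 library left out could not move that far, since the SD comes from the same 2 or 3 libraries. All 27 therefore come from the alternatives of clustering and filtering, and 27 of 282 understates how often those moved. With an estimated correlation, all 8 list calls between animals ended, of 24 lists tested, and 13 of 16 list calls between cell types, of 56 tested. Of named genes, 162 of 1735 values between animals and 76 of 4628 between cell types missed a threshold. The cause was not tested.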

Other observations

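These comparisons were chosen after the clusters were seen, and the 4 claustrum-like clusters were found in the same data. Cluster 1 was higher than the other claustrum-like clusters in the kainate subunit GRIK1 (628 ± 207 against 75.0 ± 36.1 CPM, n = 5, log2 3.44), SNTB1 (log2 3.35), the relaxin receptor RXFP1 (log2 2.44) and the transcription factor TFAP2D (log2 2.38). Cluster 3 was higher in the activity-regulated factor NPAS4 (log2 2.50), the prohormone convertase PCSK1 (log2 2.31) and the orexin receptor HCRTR2 (log2 2.25). Cluster 4 was higher in the serotonin receptor HTR4 (log2 2.32), PRKG1 (log2 1.86) and the guidance gene SEMA3A (log2 1.78). Cluster 5 was higher in the cadherin CDH7 (log2 2.76), CACNA1A (log2 2.40) and DRD2 (138 ± 16.5 against 39.7 ± 9.04 CPM, log2 1.92). HTR4, SEMA3A and CACNA1A were lower in claustrum-like neurons as a whole than in other excitatory neurons. By edgeR, 272, 217, 228 and 153 of 10521 genes were called in clusters 1, 3, 4 and 5. Clusters were formed from gene counts, so these p-values describe the clusters and do not test that they exist.

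The largest unnamed excitatory clusters were compared with claustrum-like neurons. Cluster 2, with 1514 nuclei, was higher in TOX (495 ± 78.0 against 9.33 ± 5.38 CPM, n = 5, log2 5.85), CACNA1A (log2 4.42), GRIK4 (log2 3.89) and the cadherin CDH13 (log2 3.77), and lower in FSHR (log2 -6.11), IL19 (log2 -5.49) and TSPAN18 (log2 -5.02). Cluster 6, with 656 nuclei, was higher in THBS1 (log2 6.44), CDH13 (log2 5.45) and the mu opioid receptor OPRM1 (log2 5.08), and lower in FSHR (log2 -6.68). In all, 800 of 11837 and 1140 of 11577 genes were called. Smaller clusters that stayed unnamed held 20 nuclei with the cholinergic genes CHAT, SLC5A7 and LHX8 among their top genes and 23 nuclei with TAC3.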
